A study of Mus musculus with 7 samples.

How the data were processed

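Whole lungs of male mice 3 to 4 months old were compared between claudin-18 knockout and wild type on Illumina MouseRef-8 v2 bead arrays. Per the labels, the knockout came from a floxed allele crossed to CMV-cre mice, which removed exons 2 and 3, on a mixed 129S6/SvEvTac, C57BL/6J and Balb/c background. The lungs were homogenized in Trizol and 1 µg of RNA was used, per the labels. Values were deposited for 3 knockout and 4 wild-type arrays, all on 1 slide. The labels speak of 4 replicates per genotype, and a knockout array with replicate number 4 was not analysed here. The labels do not state explicitly that each array is a separate animal, so the p-values measure only the spread between these samples.

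The deposited signal table gives, per the file headers, the mean bead intensity of each probe on a linear scale and a detection p-value for each probe and array. The deposited intensity values carry no background subtraction, since the lowest signal was above 0 on every array (114 on knockout 2, the lowest). The software that made this table is not stated. The second deposited table holds the authors' processed values on a log2-like scale, made with lumi 1.14.0 in R 2.11.1 per the submitters' processing notes. The authors' values had the same median of 8.65 in all 7 arrays, and their rank correlation with the signals was 1 on each array. The exact transformation behind the authors' log2-like values stays unknown, and they were used here only as an alternative.

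The signals were processed in R 4.3.3 with limma 3.58.1. The neqc function corrected the background with a negative-control mean and SD inferred from the detection p-values, added an offset of 16, applied quantile normalization and took log2. Of 25697 probes, 23978 carried 1 gene symbol, 0 carried several and 1719 carried none. Of the named probes, 23962 were found in the reference gene table of mouse assembly GRCm38. Probes with a detection p under 0.01 on at least 3 arrays were kept, which left 11902 probes and 8537 named genes for testing. Genotypes were compared with lmFit and eBayes, with Benjamini-Hochberg adjustment over the probes kept and a threshold of 0.05. All adjusted p-values below come from these tools. Change is given as knockout minus wild type on the log2 scale, with its standard error (SE). Figures were drawn with Python 3.11.15.

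Before the data were examined, 54 gene lists were written, and 51 had at least 5 kept genes. Lists were tested with camera at a preset correlation between genes of 0.01, with 1 probe per gene (the brightest), and adjusted over all lists tested. For each list that passed, the adjusted p from camera with an estimated correlation is given as well. Members past the threshold over all probes were counted, and so were members past it when adjusted over the list alone. A list score was the mean over its genes of each array's level minus the gene's mean over all arrays. Exact permutation p-values were taken over the 35 ways to split 7 arrays into groups of 3 and 4; they are two-sided, and with these sample numbers the smallest possible exact p is 0.0286. Genes within 100 tested genes on either side of Cldn18 on chromosome 9 were compared with all others by Fisher's exact test.

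The rule for named genes was fixed before the data were examined. It names Cldn18, the 12 largest rises and 12 largest falls among genes past the threshold with no overlap between the groups, and 25 preset genes whether changed or not. It also names up to 4 members with the largest change of each list described. Clone and predicted gene names were only counted. Genes named outside the rule are said to have been chosen after their values were seen. Where a gene was detected on no array of one genotype, the fold is given as "at least": each undetected array was raised to the lowest level at which any probe was detected on that array. A gene detected on only some arrays of a genotype has a change that includes levels not above background.

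Detected probes numbered 11715, 10646 and 10291 on the knockout arrays and 12376, 11750, 12157 and 11211 on the wild-type arrays. The means were 10884 ± 741 (SD, n = 3) and 11874 ± 512 (SD, n = 4), with an exact permutation p of 0.114. The median signal was 308 ± 45.6 (SD, n = 3) in the knockout and 411 ± 58.6 (SD, n = 4) in the wild type, with an exact permutation p of 0.0857. For arrays, the number of samples limits the precision. Of the sex-linked genes, Eif2s3y was detected on 7 arrays, Uty on 3 and Kdm5d on 0. Xist was detected on 7 arrays by ILMN_3022688 and on 1 by ILMN_3123341. Detection was thus mixed and did not check the sex given above.

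The scripts were tested on simulated data with 3 and 4 arrays and 200 changed probes among 12985. They recovered 0 of 50 probes changed 1.5-fold, 14 of 50 changed 2-fold, 45 of 50 changed 4-fold and 48 of 50 changed 8-fold. The data gave 1056 calls among 11902 probes. More calls loosen the cut in unadjusted p, so the recovered shares need not hold for the data. Of 112 simulated calls, 5 were false (4.46%), and 0 of 50 unchanged lists passed. The simulated noise was independent between probes, and the lists were drawn at random. The result for lists therefore does not cover lists of correlated genes.

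Alternatives written before the data were examined were the authors' values, no background correction, normexp with an offset of 50, median scaling, cyclic loess, no filter, and a filter over all 7 arrays. Others were a variance trend with robust fitting, array weights, the replicate number as a block, slide position as a covariate, and leaving out each array in turn. Thresholds of 1.5-fold and of treat against 1.2-fold were tried, as were camera with an estimated correlation, fry, the mean of all probes of a gene, and 50 or 200 neighbours of Cldn18. The member counts of lists without each array were added after the data were seen. The closing section gives the effect of these choices. Sequences of the probes were not available.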

Results

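Claudin-18 is a tight junction protein of the lung's alveolar epithelium, and the arrays asked which transcripts differ when it is absent. The Cldn18 transcript was lower in the knockout on every array. Its only probe, ILMN_1241689, gave a mean signal of 1280 ± 517 (SD, n = 3) in the knockout and 20112 ± 5643 (SD, n = 4) in the wild type. The knockout signals were 1875, 1030 and 935, and the wild-type signals were 18072, 14718, 27990 and 19666. The log2 change was -3.71 (SE 0.19, limma adjusted p = 4.2e-05), a 13.1-fold difference, and the exact permutation p was 0.0286 with 3 and 4 arrays. The probe was still detected on all 3 knockout arrays. Its place relative to the deleted exons is unknown, so the probe need not show the deletion itself. The fall on all 3 knockout arrays goes with the genotype labels wherever the probe lies.

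The genotypes also parted over the whole array. Correlations between arrays ran from 0.976 to 0.983 within the knockout, from 0.959 to 0.978 within the wild type and from 0.934 to 0.971 between genotypes. The first principal component held 44.4% of the variance, with the knockout at -23.3, -35.1 and -35.5 and the wild type at 35.4, 25.3, 14.9 and 18.4.

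**Figure D1:**
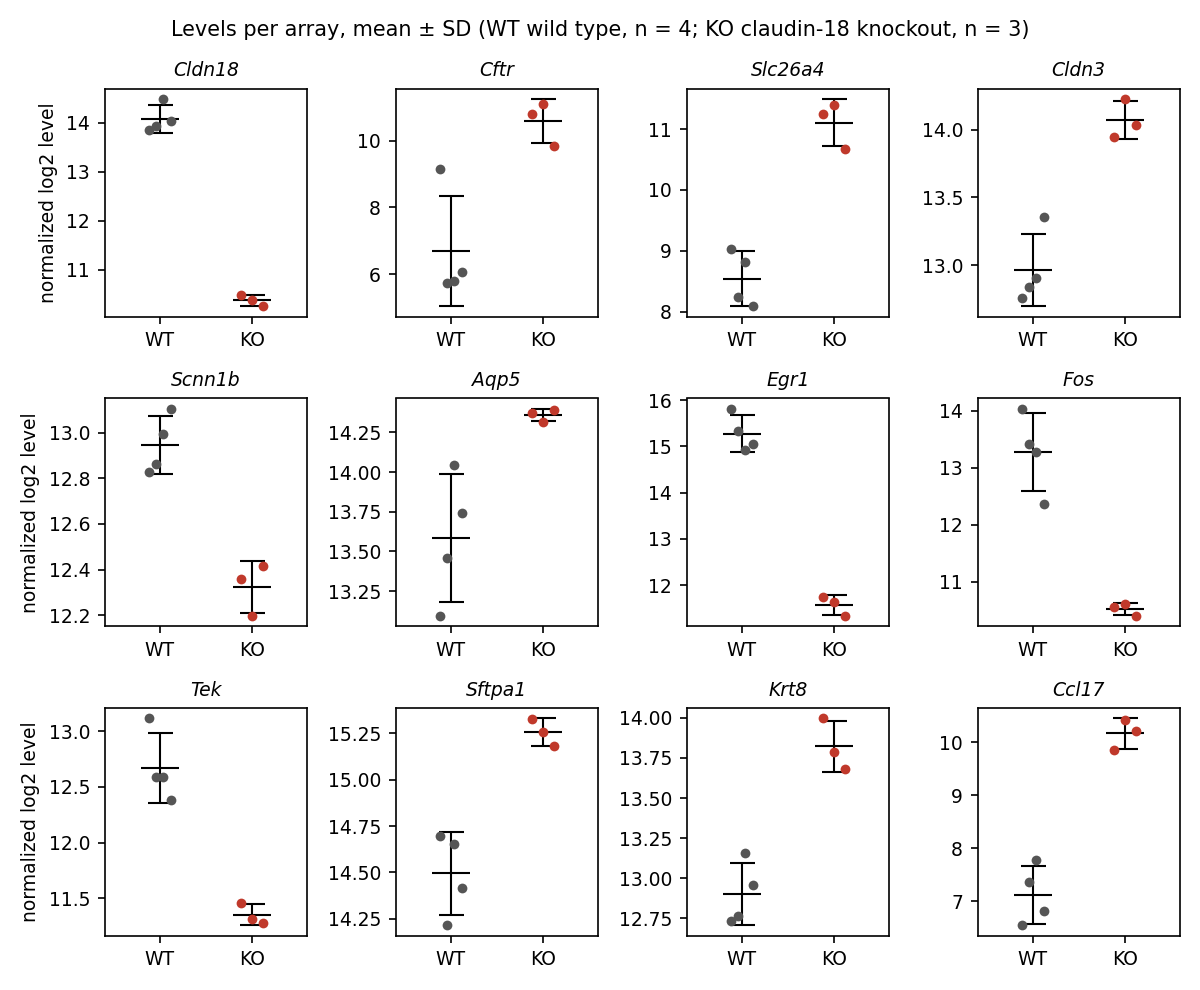
Normalized log2 level of selected genes on each of the 7 arrays (vertical axis, log2 signal), by genotype (horizontal axis). Cldn18 and the immediate-early gene Egr1 lay lower on every knockout array.

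The 12 largest rises included secreted proteins, transporters and products of dendritic cells. Kng1 encodes the kinin precursor kininogen, Pgc a secreted aspartic protease, and Chia1 a chitinase of the lung epithelium. Cftr and Slc26a4 encode anion channels or exchangers of epithelia, and Slc17a2 a sodium-phosphate transporter. Ccl17 encodes a chemokine of dendritic cells and Cd207 the lectin langerin of the same cells. The largest falls included Egr1, Fos and Ccn1, which are switched on within minutes of a stimulus, Slc4a1, the red cell anion exchanger, and Igfbp2, a binding protein for insulin-like growth factors found in type 1 cells.

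By limma, 1056 of 11902 probes passed an adjusted p of 0.05, 472 higher and 584 lower, against 3074 probes at an unadjusted p under 0.05. At least 2-fold changes made up 510 of them, 213 higher and 297 lower. In genes, 314 were higher and 436 lower, and 75 of the probes had no gene symbol. With genes split by mean level into 5 bins, the dimmest bin had 53 higher and 99 lower, and the brightest 59 and 75. Lower genes outnumbered higher ones in each bin. The groups did not overlap for 25.7% of all probes tested, where chance gives 5.71%, and for 1052 of the probes past the threshold. The count fell to 702 without knockout 1, 327 without knockout 2, 493 without knockout 3 and 694 without wild type 2. No gene had probes past the threshold in opposite directions, but 199 of 2021 genes with over 1 probe had some probes past it and some not.

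The 2 probes for Kng1 disagreed. Probe ILMN_2788223 was at least 7.11-fold higher (adjusted p = 1.0e-04), detected on 3 knockout and 0 wild-type arrays, while ILMN_2788221, detected on 2 knockout and 4 wild-type arrays, gave 0.13 (adjusted p = 0.745). Pgc was at least 8.22-fold higher (adjusted p = 0.00116), detected on 3 knockout and 0 wild-type arrays. Nnat rose by 3.16 (adjusted p = 0.000875), Ccl17 by 3.05 (adjusted p = 0.000881), Cd207 by 2.64 (adjusted p = 0.000881) and Chia1 by 2.26 (adjusted p = 0.00202). Ccl17 was detected on 2 wild-type arrays, and Nnat and Cd207 on 3 each. Psca rose by 2.22 (adjusted p = 0.00045) and Rem2 by 2.18 (adjusted p = 0.000881). Slc17a2 rose at least 3.85-fold and Azin2 at least 2.25-fold (adjusted p = 0.00032 for both), each detected on 0 wild-type arrays. With the authors' values the log2 changes were smaller for nearly all of these genes, at 1.31 for Kng1, 1.38 for Pgc, 1.45 for Nnat, 1.41 for Ccl17, 1.05 for Cd207, 0.99 for Rem2, 0.71 for Slc17a2 and 0.48 for Azin2. In all of these genes the 3 knockout arrays lay above the 4 wild-type arrays, apart from the Kng1 probe ILMN_2788221.

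Trim10, a ubiquitin ligase of red cell precursors, fell by 3.40 (SE 0.44, adjusted p = 0.00327) by a probe detected on 1 knockout and 4 wild-type arrays. Its other probe, ILMN_2477324, detected on 0 knockout arrays, was at least 1.59-fold lower (adjusted p = 0.0623). Klk1b22, a kallikrein, was at least 4.69-fold lower (adjusted p = 0.00107), and Uap1, an enzyme of amino sugar synthesis, at least 4.71-fold lower (adjusted p = 0.000334). The transcription factor Pou6f1 was at least 2.87-fold lower (adjusted p = 0.000575) and the lysosomal protein Tmem106b at least 2.72-fold lower (adjusted p = 0.00548). These 4 genes were detected on 0 knockout and 4 wild-type arrays, and with the authors' values their log2 changes were -1.08, -0.96, -0.84 and -0.87. Slc4a1 (-2.64, adjusted p = 0.0116), the axon guidance protein Sema5a (-2.54, adjusted p = 0.0145) and Igfbp2 (-2.40, adjusted p = 0.00344) fell too. Sema5a was detected on 2 knockout arrays. With the authors' values Trim10 gave -1.16, Sema5a -1.61, Bex2 -1.48 and Igfbp2 -1.80. The Sema5a log2 change had an adjusted p of 0.0535 with a variance trend and robust fitting. Bex2 fell by 2.43 (adjusted p = 0.00551), but 1 of its 3 probes, ILMN_3065164, gave 0.46 and did not pass. The 3 knockout arrays lay below the 4 wild-type arrays for each gene named here, apart from the probes ILMN_2477324 and ILMN_3065164.

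**Figure D2:**
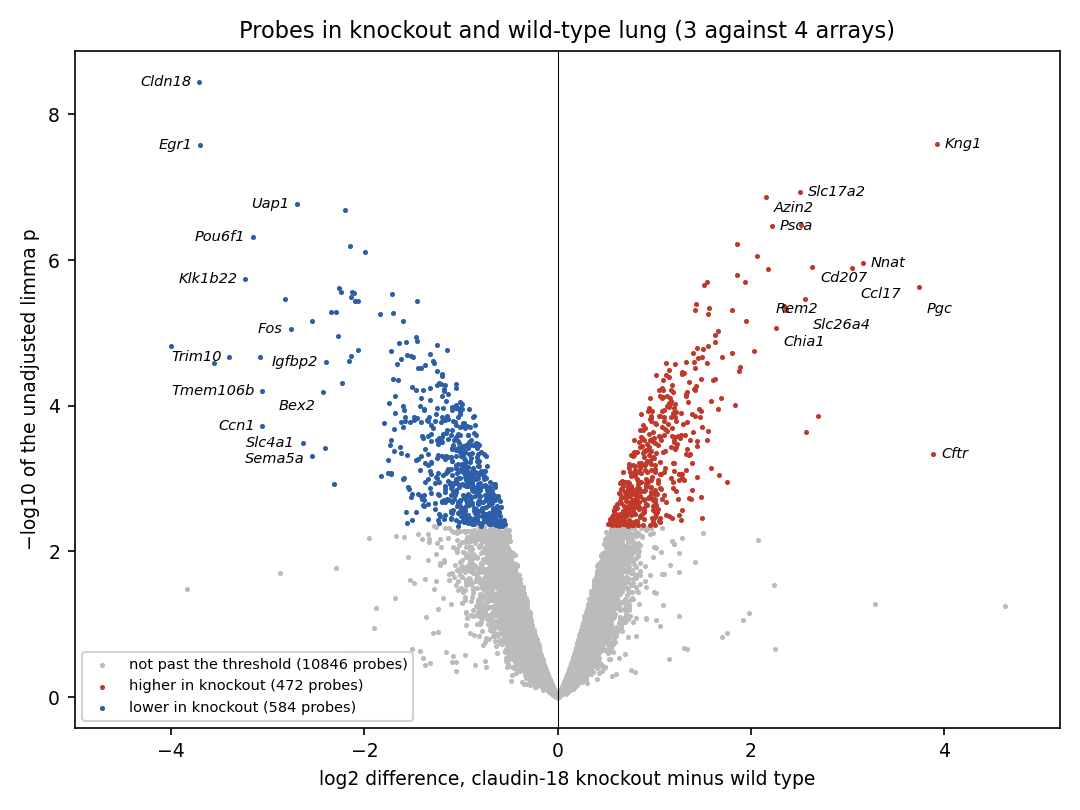
Log2 change between knockout and wild type (horizontal axis) against -log10 of the unadjusted p (vertical axis) for each probe tested. Cldn18 lies far to the left, near Egr1, and the genes with the largest changes are marked.

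Other junction proteins were asked about first, since claudins share the strands of tight junctions. Cldn3, a sealing claudin of alveolar and airway epithelium, was higher in the knockout. Lsr, the angulin of contacts between 3 cells, and Marveld3, a relative of occludin, were higher as well. Tjp1, the scaffold ZO-1 that ties claudins to actin, was lower.

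Cldn3 rose by 1.10 (SE 0.19, adjusted p = 0.00829), or 2.15-fold, Lsr by 1.05 (SE 0.17, adjusted p = 0.00779) and Marveld3 by 0.91 (SE 0.20, adjusted p = 0.0246), by limma. Tjp1 fell by 0.68 (SE 0.16, adjusted p = 0.0292). In each, the 3 knockout arrays lay on one side of the 4 wild-type arrays. The other probe for Marveld3 gave 1.01 (adjusted p = 0.073). Cldn4 (0.87, adjusted p = 0.0607), Cldn7 (0.40, adjusted p = 0.379) and Ocln (0.46, adjusted p = 0.197) did not pass, and Cldn5 has no named probe. Of 27 genes in the list, 3 were higher and 1 was lower, or 4 and 3 adjusted over the list alone. The list itself did not pass (median 0.24, camera adjusted p = 0.276). For the Tjp1 log2 change, the adjusted p was 0.142 without knockout 2, 0.0958 without knockout 3, 0.0706 without wild type 3, 0.0606 without wild type 4 and 0.0563 with the authors' values. For the Marveld3 log2 change it was 0.0898 without knockout 2, 0.0903 without knockout 3 and 0.056 without wild type 2. The Cldn4 log2 change passed without knockout 3 (adjusted p = 0.0348), and the Ocln log2 change passed without wild type 1 (adjusted p = 0.0402).

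The series title names alveolar fluid homeostasis, so transporters of sodium, chloride and water were compared. Among the members higher in the knockout were Cftr, the cyclic AMP-gated chloride channel, and Slc26a4 and Slc26a9, an exchanger and a channel of the same family. Kcnj15, an inward rectifier potassium channel, was higher too. Scnn1b, the beta subunit of the epithelial sodium channel that draws fluid out of the air spaces, was lower.

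Cftr rose by 3.89 (SE 0.75, limma adjusted p = 0.0142), Slc26a4 by 2.56 (SE 0.27, adjusted p = 0.00125), Slc26a9 by 1.35 (SE 0.21, adjusted p = 0.00668) and Kcnj15 by 1.195 (SE 0.18, adjusted p = 0.00554), or 2.29-fold. In all 4, the 3 knockout arrays lay above the 4 wild-type arrays. Cftr was detected on 3 knockout and 1 wild-type arrays, so its change rests on background levels in 3 wild-type arrays. It stood at 10.8, 11.1 and 9.84 in the knockout and at 9.16 in wild type 1, against 5.75, 5.79 and 6.07 in the other wild-type arrays. The Cftr log2 change was 1.75 with the authors' values. It had an adjusted p of 0.0619 without knockout 2 and 0.0699 with a variance trend and robust fitting. Of the 4 probes for Slc26a9, 1 gave 0.62 and did not pass. Scnn1b fell by 0.62 (SE 0.15, adjusted p = 0.0351), with no overlap between the groups. The Scnn1b log2 change had an adjusted p of 0.0863 without knockout 1, 0.165 without knockout 2, 0.0807 without knockout 3, 0.0631 without wild type 2, 0.0818 without wild type 3 and 0.0713 without wild type 4. It was 0.0951 with median scaling and 0.0556 with no filter.

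The other sodium channel subunits Scnn1g (-0.62, adjusted p = 0.0572) and Scnn1a (-0.15, adjusted p = 0.780) did not pass, nor did Atp1b1 of the sodium pump (0.42, adjusted p = 0.192). The Atp1b1 log2 change passed without wild type 1 (adjusted p = 0.036) and with median scaling (adjusted p = 0.0397). The brightest probe for the endothelial water channel Aqp1 gave -0.54 (adjusted p = 0.0927), while its other 2 probes passed, at -0.80 and -0.69. The brightest probe for Aqp5, the water channel of type 1 cells, gave 0.77 (adjusted p = 0.0597), and its other probe passed at 1.11. The Aqp5 log2 change passed without wild type 3 (adjusted p = 0.0335). Of 32 genes in the list, 6 were higher and 1 was lower, or 8 and 5 adjusted over the list alone. Besides those above, the proteases Prss8 (0.86) and St14 (0.59), chosen after their values were seen, were higher. The list did not pass (camera adjusted p = 0.276). Its median was -0.03, its mean 0.27, and camera's direction was upward. The higher members became 3 without knockout 2, and the lower ones ran from 0 with median scaling or no filter to 5 with no background correction.

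Actin genes were compared because tight junctions are anchored in the actin cortex. Add3, which caps and links cortical actin, Myh10, a nonmuscle myosin, and Palld, a scaffold of stress fibres, were lower. Capg, a capping protein abundant in macrophages, was higher. Ccn1 and Ankrd1, targets of the cell-stretch regulators YAP and TEAD, were lower as well.

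Add3 (-0.89, SE 0.19, adjusted p = 0.0227), Myh10 (-0.74, SE 0.19, adjusted p = 0.0412) and Palld (-0.67, SE 0.17, adjusted p = 0.0363) fell, and Capg rose by 0.67 (SE 0.17, adjusted p = 0.0426), by limma with no overlap between the groups. The other probe for Capg gave 0.62 (adjusted p = 0.095). Of 41 genes, 1 was higher and 3 were lower, with the same counts adjusted over the list alone. The list did not pass (median -0.10, camera adjusted p = 0.18). These 4 calls were fragile, since 0 of the list's genes passed without knockout 1, without knockout 2 or without knockout 3. The Add3 log2 change, for one, had an adjusted p of 0.059, 0.107 and 0.0544 in those fits. Myh10, Palld and Capg did not pass with no filter either. Counts without each wild-type array were 4 for wild type 1, and 2 for each of the others. The lower genes became 7 with a variance trend and robust fitting, and 1 with no filter. Ankrd1 gave -1.60 (SE 0.25, adjusted p = 0.00717), or 3.03-fold lower, and Ccn2, also a YAP target, gave -0.50 (adjusted p = 0.0983). The 15 YAP and TEAD targets had a median of -0.15 and did not pass (camera adjusted p = 0.0781).

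**Figure D3:**
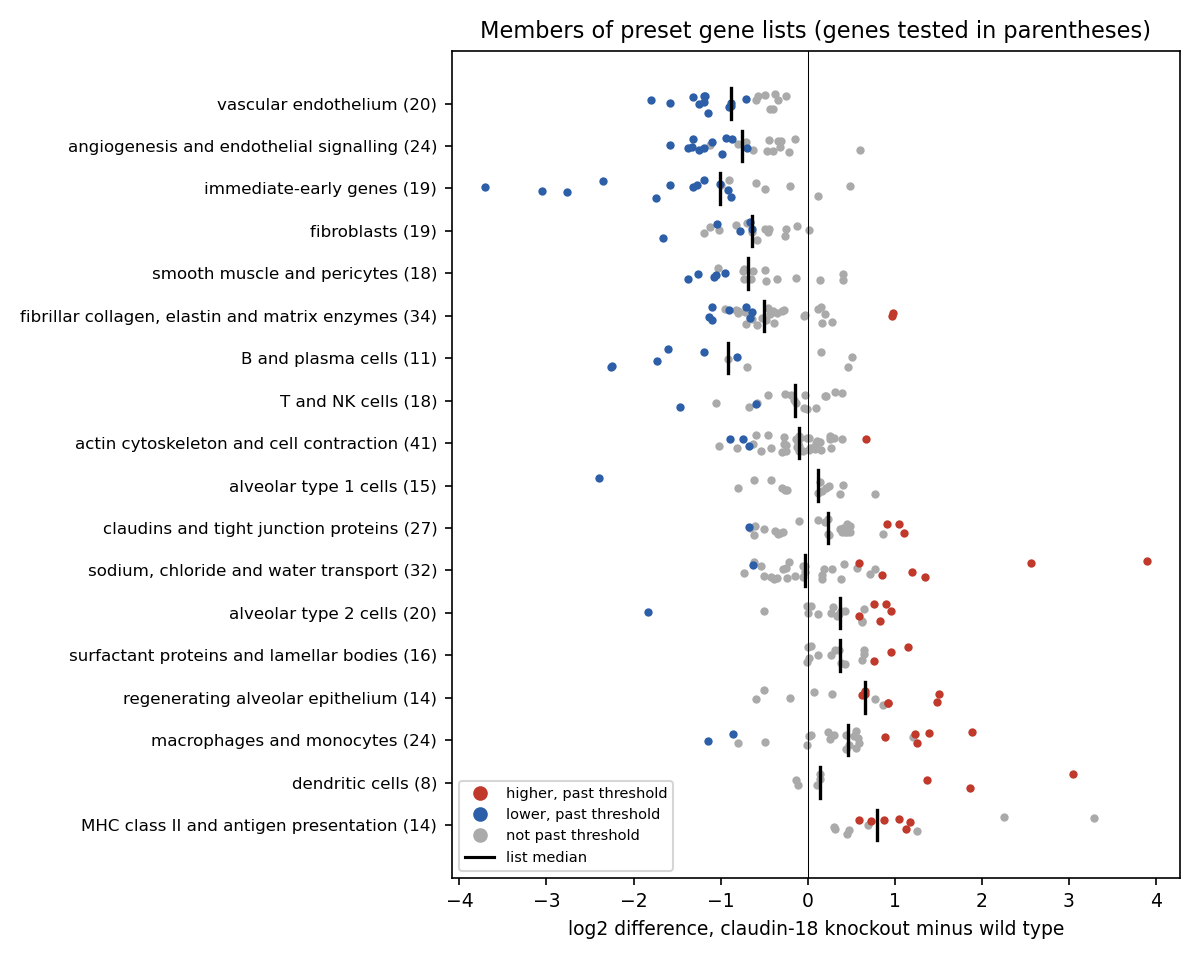
Log2 change between knockout and wild type (horizontal axis) of each tested member of selected preset gene lists (vertical axis). Endothelial, mesenchymal and immediate-early lists lie to the left, and antigen presentation to the right.

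Across all lists, 20 of 51 passed with the preset correlation, 9 higher and 11 lower, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.132. Vascular and mesenchymal genes were among those lower. Tie1 and Tek encode the angiopoietin receptors of endothelium, Calcrl the receptor part for adrenomedullin, and Eng an endothelial co-receptor for TGF-beta. Flt1 and Vegfd belong to the VEGF system. Pdgfra marks lung fibroblasts, and Notch3, Gucy1b1 and Pdgfrb mark smooth muscle and pericytes.

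Vascular endothelium had 12 of 20 genes lower and 0 higher, or 15 adjusted over the list alone (median -0.88, camera adjusted p = 2.4e-11, against an adjusted p = 0.132 with an estimated correlation). Calcrl (-1.79, SE 0.30, adjusted p = 0.0084), Tie1 (-1.58, SE 0.26, adjusted p = 0.00779), Tek (-1.32, SE 0.19, adjusted p = 0.00539) and Eng (-1.25, SE 0.20, adjusted p = 0.00723) fell, each with the 3 knockout arrays below the 4 wild-type arrays. Angiogenesis, which shares 6 genes with that list, had 11 of 24 lower and 0 higher, or 16 lower and 1 higher adjusted over the list alone (median -0.76, adjusted p = 2.6e-09, against an adjusted p = 0.204 with an estimated correlation). Flt1 fell by 1.37 (SE 0.18, adjusted p = 0.00349), with its other probe at -0.78 and not past the threshold, and Vegfd fell by 1.33 (SE 0.22, adjusted p = 0.00779). The 11 became 7 without knockout 2.

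Fibroblast genes had 5 of 19 lower and 0 higher, or 12 adjusted over the list alone (median -0.64, camera adjusted p = 1.0e-06, against an adjusted p = 0.132 with an estimated correlation). Scube2, a secreted hedgehog carrier, fell by 1.66 (SE 0.22, adjusted p = 0.00349) and Pdgfra fell by 1.04 (SE 0.23, adjusted p = 0.0231). The Pdgfra log2 change had an adjusted p of 0.0543 without knockout 1, 0.071 without knockout 2, 0.0863 without knockout 3 and 0.0544 without wild type 3. Smooth muscle and pericytes had 5 of 18 lower and 0 higher, or 10 adjusted over the list alone (median -0.69, adjusted p = 4.9e-05, against an adjusted p = 0.204 with an estimated correlation). Gucy1b1 (-1.26, SE 0.21, adjusted p = 0.00773), Notch3 (-1.08, SE 0.18, adjusted p = 0.00832) and Pdgfrb (-1.37, SE 0.26, adjusted p = 0.0129) fell. The Pdgfrb log2 change had an adjusted p of 0.0636 without knockout 2 and 0.0523 without knockout 3. The 5 fibroblast genes became 2 without knockout 1, 1 without knockout 2, 2 without knockout 3 and 3 without wild type 2, and the 5 smooth muscle genes 2 without knockout 2 and 3 without knockout 3. With other processing the fibroblast count ran from 3 with no filter to 9 with no background correction, and the smooth muscle count rose to 9 with a variance trend and robust fitting.

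Matrix genes, with 5 shared with the fibroblast list, had 7 of 34 lower and 2 higher, or 12 and 2 adjusted over the list alone (median -0.50, camera adjusted p = 0.000173, against an adjusted p = 0.204 with an estimated correlation). Col5a1, a collagen that starts fibrils, fell by 1.13 (SE 0.20, adjusted p = 0.0111) and elastin, Eln, fell by 1.10 (SE 0.29, adjusted p = 0.0438). Mfap5, a microfibril protein, rose by 0.98 (SE 0.19, adjusted p = 0.0151). The 2 higher genes became 0 without knockout 2 or knockout 3, and 1 without knockout 1, wild type 2 or wild type 3. The 7 lower genes became 3 without knockout 1, 1 without knockout 2, 1 without knockout 3, 3 without wild type 2 and 4 without wild type 4. They became 2 with no filter and 11 with a normexp offset of 50. The Eln log2 change had an adjusted p of 0.102, 0.123 and 0.116 without knockout 1, 2 and 3, 0.0913 without wild type 2, 0.0607 without wild type 3, 0.052 with the authors' values and 0.0778 with no filter. The Col5a1 log2 change had 0.0575 without knockout 2, and the Mfap5 log2 change 0.0658 without knockout 2 and 0.0602 without knockout 3.

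Immediate-early genes respond within minutes to growth factors, stretch or handling of tissue. Egr1 and Egr2 are zinc finger factors, Fos and Junb are parts of AP-1, and Ccn1 is a secreted matrix protein induced with them. Egr1 (-3.71, SE 0.23, adjusted p = 1.0e-04), Ccn1 (-3.06, SE 0.53, adjusted p = 0.00902), Fos (-2.76, SE 0.33, adjusted p = 0.00204) and Egr2 (-2.35, SE 0.26, adjusted p = 0.00142) fell, by limma. Of the other 2 probes for Ccn1, 1 gave -4.01 and the other, detected on 0 knockout arrays, was at least 4.25-fold lower. Egr1 stood at 14.9 to 15.8 in the wild type, near the top of the scale, where a change can be understated. In each gene the 3 knockout arrays lay below the 4 wild-type arrays. Of 19 genes, 12 were lower and 0 higher, or 14 adjusted over the list alone (median -1.01, camera adjusted p = 9.1e-11, against an adjusted p = 0.132 with an estimated correlation). Heat shock genes, the other list for stress of handling, did not pass (median 0.12, adjusted p = 0.211).

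Epithelial genes moved upward in part. Clu, a chaperone, Lcn2, a siderophore-binding protein, and the simple keratins Krt8 and Krt18 belong to the list for regenerating alveolar epithelium. Whether the epithelium was under repair was not tested. Napsa and Ctsh are proteases that process surfactant proteins in type 2 cells, and Sftpa1, Sftpb and Sftpc are surfactant proteins themselves. Ager and Pdpn mark type 1 cells, Scgb1a1 club cells and Foxj1 ciliated cells.

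Regenerating epithelium had 7 of 14 genes higher and 0 lower, or 9 and 2 adjusted over the list alone (median 0.66, camera adjusted p = 0.000582, against an adjusted p = 0.267 with an estimated correlation). Clu rose by 1.51 (SE 0.19, adjusted p = 0.0031), Lcn2 by 1.48 (SE 0.21, adjusted p = 0.00461), Krt18 by 0.92 (SE 0.18, adjusted p = 0.0162) and Krt8 by 0.92 (SE 0.17, adjusted p = 0.0119), with no overlap between the groups. The Krt8 log2 change had an adjusted p of 0.0542 without knockout 2, and the Krt18 log2 change had 0.0502, 0.065 and 0.0559 without knockout 1, 2 and 3. The 7 became 3 without knockout 1, 2 without knockout 2, and 4 without knockout 3, wild type 2 or wild type 4.

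Surfactant genes had 3 of 16 higher and 0 lower, or 4 adjusted over the list alone (median 0.37, camera adjusted p = 0.000652, against an adjusted p = 0.365 with an estimated correlation). Ctsh rose by 1.16 (SE 0.18, adjusted p = 0.00685), Napsa by 0.96 (SE 0.15, adjusted p = 0.00615) and Sftpa1 by 0.76 (SE 0.17, adjusted p = 0.0246), while Sftpb (0.43, adjusted p = 0.182) did not pass. Napsa stood at 15.6 to 15.8 in the knockout, near the top of the scale as well. Ctsh is also one of the 16 genes near Cldn18 on chromosome 9 that passed. Sftpc (0.11, adjusted p = 0.679) stood at 15.7 to 16.1 on all arrays, near the top of the scale, where the probe says little about a change. The Sftpa1 log2 change had an adjusted p of 0.0766, 0.102 and 0.0668 without knockout 1, 2 and 3, 0.056 without wild type 2 and 0.0533 without wild type 4. Type 2 cells, which share 11 genes with that list, had 5 of 20 higher and 1 lower, also adjusted over the list alone (median 0.37, adjusted p = 0.000894, against an adjusted p = 0.420 with an estimated correlation). The lower gene was Fabp5, a fatty acid binding protein, which fell by 1.83 (SE 0.39, adjusted p = 0.021). It was detected on 1 knockout array, and the Fabp5 log2 change was -0.55 with the authors' values. The 5 became 2 without knockout 1, 1 without knockout 2, and 2 without wild type 2 or wild type 4.

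Type 1 cells did not pass (median 0.12, mean -0.17, camera downward, adjusted p = 0.587). Ager (0.37, adjusted p = 0.233) and Pdpn (0.24, adjusted p = 0.401) did not pass, Igfbp2 was the only one of 15 genes past the threshold over all probes, and Hopx was detected on 0 arrays. Adjusted over the list alone, 1 gene was higher and 3 were lower. Club cells passed as a list with 0 of 15 members past the threshold either way (median -0.37, camera adjusted p = 0.0197). They had an adjusted p = 0.549 with an estimated correlation, and 0.132 without knockout 2. With median scaling their adjusted p was 0.391, and with cyclic loess 0.0565. Scgb1a1 gave 0.04 (adjusted p = 0.895) but stood at 15.9 to 16.1, near the top of the scale as well. Ciliated cells did not pass (adjusted p = 0.848), nor did Foxj1 (-0.39, adjusted p = 0.363).

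Lists of immune cells were compared in turn. Cd86 is a co-stimulator of T cells, H2-DMa and H2-DMb1 load peptides on MHC class II molecules, and H2-Ab1 is a class II chain. Itgae marks a subset of dendritic cells, and Ear10 and Ctsk are products of macrophages. Fcmr, Fcrla and Cd79a are B cell genes, and Cd27 is a receptor of T and B cells.

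Antigen presentation had 6 of 14 genes higher and 0 lower, or 8 adjusted over the list alone (median 0.80, camera adjusted p = 1.1e-06, against an adjusted p = 0.229 with an estimated correlation). Cd86 rose by 1.17 (SE 0.17, adjusted p = 0.00541), H2-DMb1 by 1.13 (SE 0.16, adjusted p = 0.00429), H2-DMa by 1.05 (SE 0.19, adjusted p = 0.0106) and H2-Ab1 by 0.87 (SE 0.18, adjusted p = 0.0173), with no overlap between the groups. Of the 4 probes for H2-Ab1, 3 passed. The other, ILMN_1226525, gave 4.63 (adjusted p = 0.206), with wild type 1 to 4 at 6.59, 5.95, 15.4 and 14.3. The H2-DMa log2 change had an adjusted p of 0.0527 without knockout 2, and the H2-Ab1 log2 change had 0.0792 without knockout 2 and 0.0632 without knockout 3. The 6 became 2 without knockout 2 and 3 without knockout 3.

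Dendritic cells had 3 of 8 higher and 0 lower, the same adjusted over the list alone (median 0.14, mean 0.80, camera adjusted p = 0.0149, against an adjusted p = 0.256 with an estimated correlation). Itgae rose by 1.86 (SE 0.16, adjusted p = 0.00064), with Ccl17 as given above, and Ffar2, a receptor for short fatty acids, by 1.37 (SE 0.26, adjusted p = 0.0141). The Ffar2 log2 change had an adjusted p of 0.069 without knockout 2. The dendritic list had an adjusted p of 0.103 with no filter and 0.0549 with probes detected on all arrays. Macrophages had 5 of 24 higher and 2 lower, or 8 and 3 adjusted over the list alone (median 0.46, camera adjusted p = 0.00582, against an adjusted p = 0.392 with an estimated correlation). Ear10 rose by 1.40 (SE 0.28, adjusted p = 0.0167) and Ctsk by 1.26 (SE 0.27, adjusted p = 0.0223). The lower genes, chosen after their values were seen, were Cx3cr1 (-1.14) and Cd163 (-0.85). The Ear10 log2 change had an adjusted p of 0.0595 without knockout 2 and 0.06 without knockout 3, and the Ctsk log2 change had 0.0706 without knockout 1, 0.0976 without knockout 2 and 0.053 without wild type 4. The 5 became 3 without knockout 1, 1 without knockout 2 and 3 without knockout 3, and the 2 lower genes became 0 without knockout 2 or wild type 2.

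B and plasma cells had 6 of 11 genes lower and 0 higher, or 8 lower and 1 higher adjusted over the list alone (median -0.91, camera adjusted p = 0.000368, against an adjusted p = 0.256 with an estimated correlation). Fcmr (-2.26, SE 0.23, adjusted p = 0.00116) and Fcrla (-2.24, SE 0.23, adjusted p = 0.00121) fell, and Cd79a gave -1.60 (SE 0.18, adjusted p = 0.00168), or 3.04-fold lower, with no overlap between the groups. Fcrla was detected on 1 knockout array and Cd79a on 2. The 6 became 3 without knockout 2, without knockout 3, or with probes detected on all arrays. Over the other settings the log2 change ran from -3.18 to -1.28 for Fcmr, -3.02 to -0.74 for Fcrla and -1.79 to -0.61 for Cd79a. T and NK cells had 0 of 18 higher and 2 lower and did not pass (median -0.15, adjusted p = 0.12), though Cd27 fell by 1.46 (SE 0.22, adjusted p = 0.00541). Neutrophils did not pass (adjusted p = 0.848).

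Acute phase genes had 7 of 31 higher and 0 lower, or 9 and 3 adjusted over the list alone (median 0.12, camera adjusted p = 0.0476, against an adjusted p = 0.256 with an estimated correlation). Tlr2, a receptor for bacterial lipoproteins, rose by 1.10 (SE 0.18, adjusted p = 0.00725) with no overlap between the groups. Lcn2 and Ccl17 were members as well. The list had an adjusted p of 0.0575 without knockout 1, 0.079 without knockout 2, 0.133 without wild type 1, 0.0722 without wild type 3 and 0.062 without wild type 4. It was also lost with the authors' values (0.0673), no background correction (0.0519), no filter (0.132), probes detected on all arrays (0.0955) and array weights (0.0748), and so was kept in 6 of 16 settings. The 7 became 3 without knockout 1, knockout 2 or wild type 2.

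Blood and growth genes made up further lists. Cdk1 drives entry into mitosis and Tyms makes thymidylate. Cell cycle genes had 4 of 19 higher and 0 lower, or 5 adjusted over the list alone (median 0.28, camera adjusted p = 0.0252). They had an adjusted p = 0.549 with an estimated correlation, 0.0861 without knockout 2 and 0.161 without wild type 1. The list was lost as well with the authors' values (adjusted p = 0.0542), no filter (0.0546) and probes detected on all arrays (0.0955). Cdk1 rose by 1.46 (SE 0.23, adjusted p = 0.00723) and Tyms by 1.27 (SE 0.23, adjusted p = 0.0108), with 1 of the other 2 Tyms probes not past the threshold. The 4 became 2 without knockout 2.

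Platelet genes had 2 of 10 lower and 0 higher, or 7 adjusted over the list alone (median -1.18, camera adjusted p = 0.000368, against an adjusted p = 0.457 with an estimated correlation). Alox12, a platelet lipoxygenase, fell by 1.34 (SE 0.33, adjusted p = 0.0333) and Gp5, a glycoprotein of the von Willebrand receptor, fell by 1.31 (SE 0.30, adjusted p = 0.0278). Both calls were lost with no filter, and that of Gp5 also with the authors' values. The 2 became 0 without knockout 2, wild type 1 or wild type 4, 1 without knockout 3 or wild type 2, 7 without wild type 3, and 4 with a normexp offset of 50. Red cells had 3 of 11 lower and 1 higher, or 7 and 1 adjusted over the list alone (median -0.93, adjusted p = 0.0183). They had an adjusted p = 0.457 with an estimated correlation, 0.0858 without wild type 1 and 0.182 with probes detected on all arrays, where the 3 became 1.

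Oxidative phosphorylation passed with 0 of 50 genes past the threshold either way (median 0.20, camera adjusted p = 0.00357). It had an adjusted p = 0.631 with an estimated correlation, 0.147 without wild type 1 and 0.0977 with array weights. Cardiac muscle, which enters lung samples with the sleeves of the pulmonary veins, had 1 of 20 higher and 0 lower, or 1 and 2 adjusted over the list alone (median -0.53, adjusted p = 0.0128). It had an adjusted p = 0.549 with an estimated correlation, 0.0848 without knockout 2 and 0.0803 without wild type 2. The higher gene was Cox6a2, a muscle form of a cytochrome oxidase subunit (0.81, SE 0.19, adjusted p = 0.0308), which opposes the list's direction. The Cox6a2 log2 change had an adjusted p of 0.102 without knockout 1, 0.141 without knockout 2, 0.0539, 0.0554, 0.0584 and 0.0662 without wild type 1, 2, 3 and 4, and 0.0534 with no filter. Wild type 2 also carried skeletal muscle genes at a score of 3.79, against -0.69 to -0.19 in the other wild-type arrays, and that list did not pass (adjusted p = 0.0905).

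Genes near the targeted locus were compared because alleles linked to it can differ between genotypes on a mixed background. Of the 200 tested genes around Cldn18 on chromosome 9, 16 passed the threshold (8.0%), against 732 of 8333 other genes (8.78%). The odds ratio was 0.903 with a 95% interval of 0.503 to 1.52 (Fisher's exact p = 0.80, n = 3 and 4 arrays).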

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

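The tests of endothelial content and of processing in the immediate-early genes, the tests of the endothelial and mesenchymal genes, and the tests of strain variants in on or off genes, Cftr and antigen presentation were chosen only after those results were seen. Levels and list scores of the 4 wild-type arrays were scanned with Dixon's rule for 1 array far from the others, and the knockout group of 3 was not scanned. Of 165 values examined, 8 stood apart, where chance alone marks about 5%. The number of such values was thus near that given by chance.

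Wild type 1 stood apart in Cftr at 9.16, against 5.75 to 6.07 in the other wild-type arrays. It also stood apart in the sodium pump subunit Atp1b1, at 13.9 against 13.3 to 13.4, and in the pericyte receptor Pdgfrb, at 8.82 against 9.34 to 9.44. Wild type 4 stood apart in the sodium channel subunit Scnn1a, at 13.6 against 12.6 to 12.7. Wild type 3 stood apart in the score of YAP and TEAD targets, at 0.416 against 0.088 to 0.135, and in that of dendritic cells, at -0.118 against -0.433 to -0.402. Wild type 2 stood apart in the score of skeletal muscle genes, at 3.79 against -0.688 to -0.188, and in that of basal cells, at 3.30 against -0.691 to -0.334.

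The whole count of probes was set against 3 technical readings written before the data were examined. Of the 35 splits of 7 arrays into 3 and 4, only 1, the real one, gave as many as 1056 probes, and the highest other gave 3. Each other split mixed the genotypes in at least 1 group, which widens the spread within groups. Its low counts are therefore not those of arrays without a difference. All knockout arrays lay at positions before all wild-type arrays on the slide. The change predicted from the slope over position within the groups had a median ratio to the observed change of -0.143 (SD 0.108 over 100 shuffles), which speaks against a linear position effect as the source, but an effect that jumps between positions stays open. Of the called genes, 17.8% had a called neighbour of another gene family, against a mean of 16.1% and a central range of 12.6% to 19.7% in 10000 shuffles. The calls were thus not clustered between adjacent genes beyond the shuffles. Variants that change single genes, with unchanged genes between them, would not cluster, so strain variants stay open as a source of calls.

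The fall of immediate-early genes could follow from fewer endothelial cells, from the processing, or from how and when the lungs were taken. The list's score fell further than that of vascular endothelium, with a difference of -0.409 (95% interval -0.796 to -0.0226, exact permutation p = 0.0286, n = 3 and 4). The falls of both lists had been seen before, so that p decides nothing. Their medians were -1.01 and -0.88, and fewer endothelial cells stay open as a cause. Under 5 other processings the median change of the immediate-early genes kept at least 0.812 of its size, which speaks against the processing. Clock genes of opposite phases, 7 and 3 genes, differed by 0.769 (95% interval 0.0603 to 1.48, exact permutation p = 0.0571, n = 3 and 4). Of the 7, Per2 (1.45) and Ciart (1.12) were higher past the threshold by 1 of 2 probes each. Dbp (0.56), Tef (0.21), Nr1d2 (0.19), Per1 (0.10) and Nr1d1 (-0.07) did not pass. Of the 3, Arntl (-0.73), Clock (-0.38) and Nfil3 (0.33) did not pass. The preset circadian clock list did not pass either (median 0.20, camera adjusted p = 0.115). A difference in the time of day stays open. Handling, on which the labels are silent, and a change in signalling in the lung were not tested.

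The fall of endothelial and mesenchymal genes could be a dilution by other cells, a product of the processing, or a change in those cells or their number. Against all 14 other cell type lists that did not rise, their score differed by -0.248 (95% interval -0.645 to 0.148, exact permutation p = 0.2, n = 3 and 4). Without wild type 2, which stood far above the others in muscle and basal cell genes, the score differed by -0.368 (95% interval -0.568 to -0.169, exact permutation p = 0.1, n = 3 and 3). With 3 and 3 arrays, 0.1 is the smallest possible exact p, so that p could not pass. Against ciliated, T and NK, and type 1 cells alone, picked after their values were seen, the difference was -0.553 (95% interval -0.762 to -0.344, exact permutation p = 0.0286, n = 3 and 4), but B cells, red cells and platelets fell as well, so dilution stays open. Under 5 other processings the median change of each list kept at least 0.629 of its size. Fewer such cells in the sample, less of each transcript per cell and uneven sampling of the lung remain possible, and whole-lung arrays do not tell them apart.

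Strain variants of the mixed background may lie behind genes that were on or off between wild-type arrays, 25 of which had a gap of at least 8-fold. Of these, 9 had another such gene of another family among the 10 nearest on either side, against a mean of 1.35 and a highest value of 10 in 10000 shuffles (permutation p = 3.0e-04), as linked variants could give. Of the 25, 14 were high only in wild type 2, among them the neighbouring skin genes Lor, Lce1c and Them5, which might come from attached tissue; without these 14, 6 of 11 had such a neighbour (shuffle mean 0.259, permutation p = 1.0e-04), and 7 of the 11 lie on chromosome 17. Cftr and its neighbour Wnt2, chosen after its values were seen, are 2 of the 25, both high only in wild type 1 of the 4; Wnt2 prompted the comparison with other genes (Fisher's exact p = 0.00234, n = 4 wild-type arrays), so that p decides nothing, and whether strain or loss of claudin-18 set Cftr stays open. The antigen presentation list had 5 genes on other chromosomes than H2-Ab1, and their score was higher by 0.57 (95% interval 0.282 to 0.857, exact permutation p = 0.0286, n = 3 and 4). All 14 genes of the list had been seen to have positive changes, so that p decides nothing. Of the 5, Cd86 (1.17) and Cd74 (0.59) passed, while Ciita (0.47), Cd83 (0.31) and Ctss (0.31) did not. The rise was thus not limited to the chromosome of H2-Ab1, and the part of variants at that locus stays open.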

How the results depend on the processing

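No test in this part was chosen after the result was seen, apart from the member counts of lists without each array. Cldn18 was lower and past the threshold under every setting, and the probes past the threshold kept their sign under every other processing and without each array. Under other processings, other filters and a variance trend the count of 1056 lay between 784 with no filter and 1395 with a variance trend and robust fitting, and the authors' values gave 1098. Calls that were higher made up 44.7% in the main analysis, 52.9% with median scaling and 41.3% with cyclic loess. Treat against 1.2-fold, a stricter test, left 372 probes (170 higher, 202 lower). Array weights gave 1876 (882 higher, 994 lower), and more than 1.5 times as many genes in several lists, such as 5 higher and 4 lower for tight junctions, and the cause was not tested. Without each array in turn the count ran from 327 to 1045, with 135 to 488 higher and 192 to 557 lower, where fewer samples were used. Slide position as a covariate left 16 (6 higher, 10 lower), because position and genotype correlate at -0.869 and the median SE grew 2.02-fold. The changes themselves did not shrink, with a median of 114% of their main size. That value follows from the slope over position within groups given above, for the same probes, and is no separate test.

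With the replicate number as a replicate block, 401 probes passed (173 higher, 228 lower). The labels state no pairing, and deviations from the group means correlated at -0.022, -0.0044 and -0.14 between arrays with the same number, so no pairing was taken from the numbers.

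Of the 20 lists past the threshold, 0 stayed with an estimated correlation, which allows for correlated genes, and 14 with fry. Fry also passed transport (adjusted p = 0.0458, upward), gap junctions (0.0135), TGF-beta targets (0.0458) and T and NK cells (0.00967), the last 3 downward. Fry asks whether the genes of a list changed, while camera compares them with all other genes, so a list can pass fry alone. Whether that is the cause here was not tested. Cytosolic ribosomal proteins, with a downward adjusted p of 0.987, turned upward with median scaling (median 0.42, adjusted p = 0.000622), and the cause was not tested. Of 134 named calls, 121 stayed with the authors' values, 112 with no filter, 74 with the replicate block, 70 without knockout 2 and 11 with slide position. With the authors' values the named calls had a median of 65.6% of their main size, and 70 of the 134 shrank over 1.5 times. Neighbours of Cldn18 passed under no setting. Where the signal did not exceed background in 1 genotype, folds are lower bounds under the main processing only, since other background steps gave smaller changes, and no comparison of precision by signal was made.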

Other observations

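Each gene and group in this paragraph and the next was chosen after its values were seen. Cdh5, the cadherin of endothelial contacts, gave -1.20 (SE 0.17, adjusted p = 0.00434), and Gja5, the arterial connexin, -1.39 (SE 0.21, adjusted p = 0.00541), with 1 of its other 2 probes, detected on 0 knockout arrays, at least 1.09-fold lower and not past the threshold (adjusted p = 0.138). Adherens junctions (adjusted p = 0.405) and gap junctions (adjusted p = 0.390) did not pass as lists. Cdh16, a cadherin of kidney-type epithelium, rose by 1.61 (SE 0.23, adjusted p = 0.00469). Sesn2, a stress-induced target of p53, rose by 1.17 (SE 0.22, adjusted p = 0.0126). The Sesn2 log2 change had an adjusted p of 0.0606 without knockout 2. Of the clock genes, Per2 rose by 1.45 (SE 0.27, adjusted p = 0.0123) and Ciart by 1.12 (SE 0.29, adjusted p = 0.0418), while the other probe of each did not pass (1.01, adjusted p = 0.0741, and 1.29, adjusted p = 0.0617). The Ciart log2 change had an adjusted p of 0.0754, 0.0828 and 0.143 without knockout 1, 2 and 3, 0.0572, 0.0534 and 0.0818 without wild type 1, 2 and 3, and 0.0757 with no filter.

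Genes known best from liver or stomach were among those higher in the knockout. From liver these were the coagulation factors F7 (1.89) and F10 (1.42), the kininogen Kng2 (1.48) and the complement protein C6 (1.40), while 5 tested genes that are abundant in liver had a median of -0.11 and 0 calls. From stomach these were the gastric lipase Lipf (1.56), intrinsic factor Cblif (1.17) and ghrelin, Ghrl (1.01), beside Pgc and Psca, while 6 other tested stomach genes had a median of -0.14 and 0 calls. F7, Kng2 and Cblif were each detected on 1 wild-type array. Some class II probes were on or off between wild-type arrays. This held for 1 of 4 probes for H2-Ab1, while the other 3 stood between 13.4 and 14.9 on all wild-type arrays. H2-Aa stood at 6.08 and 6.11 in wild type 1 and 2 and at 12.7 and 11.4 in wild type 3 and 4, and H2-Ea at 14.9, 15.2, 6.82 and 14.2 in wild type 1 to 4. Wnt2 stood at 9.92, 9.59 and 8.77 in the knockout and at 10.1, 6.44, 5.78 and 6.41 in wild type 1 to 4 (adjusted p = 0.143).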
